A study of Arabidopsis thaliana with 12 samples.

How the data were processed

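The series consists of 12 array samples of total RNA from wild-type Arabidopsis thaliana plants, 6 treated with water and 6 treated for 30 min in MS with 60 mM sucrose, per the labels. The labels give no tissue, growth conditions, labelling, batch or duration of the water treatment. Groups and replicate numbers were taken from the sample titles and source names.

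The authors deposited 1 intensity per probe and sample on a linear scale, in 1 table of 3439 probes with probe numbers up to 4607. How the authors made these intensities, that is the background correction, scaling and averaging of spots, is not given in the sources used here. Values run from 0 to 100, 252 probes are 0 in all 12 samples, 9 probes reach 100 in some sample (within 0.0005, with 99.8 the highest value below), and 2805 are above 0 in all samples. The unit of the scale, and whether arrays had been scaled, stay unknown. Medians per sample lay between 0.171 and 0.188 in water and between 0.422 and 0.459 in sucrose medium, so the table was not taken as normalised between arrays. Values below background could not be told from the table, and values of 0 were treated as missing.

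Intensities were transformed to log2 and quantile normalised between arrays. Probes with at least 4 values above 0 in each group were tested, 2915 in all, which left out 524. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Fold changes are sucrose medium over water. Values per group are mean ± SD over 6 samples, and log2 fold changes carry SE. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

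Gene names came from the platform annotation, which can be old, updated through gene identifiers to the assembly TAIR10.1. Of the probes, 692 carried 1 gene, 870 several and 1877 were not listed; 690 of the 692 matched a locus, and 584 loci were tested. A probe with several genes was not used to name a gene. AT2G25870 alone had more than 1 tested probe, and it is not among the genes described elsewhere. Named genes followed a rule set before the data were examined: the 12 largest positive and 12 largest negative log2 fold changes among probes past the threshold that name 1 gene and have a value in all 12 samples, and up to 4 members per gene list with the smallest p.

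Gene lists were tested with camera on 563 genes with a value in all samples, with a preset correlation of 0.01 between genes, and with fry. Lists of at least 3 measured genes were tested. Of 28 lists with 560 loci, fixed before the data were examined, 5 loci were on tested probes that name 1 gene and 12 only on probes with several genes. Measured genes existed for photosynthesis, Calvin cycle and hypoxia; the other 25 lists had 0, among them sugar-induced, sugar-starvation, nitrate response, sugar transport, circadian clock, and the root, epidermis and seed markers. The 14 further groups were written from the gene names of the array after values of the strongest genes had been seen, and their members are named by the same limit of up to 4 per group.

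Whether the replicate numbers pair the samples was checked from the deviations of each sample from its group mean. Same-numbered samples of the 2 groups correlated at 0.280 to 0.450 in all 6 pairs (2805 probes; across probes, which are not independent replicates). Samples of the 2 groups with other numbers but from the same set (1 and 2, 3 and 4, or 5 and 6) correlated at 0.162 to 0.282. Those from other sets correlated at -0.290 to 0.045, so part of the likeness belongs to the set and not to the number. The numbers were taken as pairing the samples on this evidence, since the labels do not say what a number stands for. The main fit has no block, and the fit with the number as a block is an alternative. Within groups, samples 1 and 2, 3 and 4, and 5 and 6 were closest, with Spearman correlations of 0.957 to 0.967 in water and 0.979 to 0.986 in sucrose medium, against 0.916 to 0.948 and 0.915 to 0.959 for other pairs. Samples of different groups correlated at 0.741 to 0.801. These sets of 2 may hold repeat measurements, which the labels do not state, so a count with 3 averaged values per group is given as well.

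The steps were tested on simulated data with 200 of 2915 probes changed. With independent noise the fit for sucrose medium against water recovered 93.0% of changes of 1 on the log2 scale and 49.0% of changes of 0.5, with 10 false calls. With noise shared within the sets of 2, at the median share of 56.4% seen in the data, it recovered 92.0% and 57.0% with 61 false calls, and the fit on 3 averaged sets 73.0% and 11.0% with 6. With no probe changed and noise shared within sets, 13.8% of unadjusted p-values of the 12-sample fit were under 0.05, so those p-values would be too small if the sets are repeats. With independent noise and no other gene changed, a group of 15 genes shifted by 0.5 was recovered by camera, and 0 of 13 other groups were. In the data 64.4% of the probes tested differed, so the other genes spread far more than in this simulation. It therefore does not show how well camera finds such a shift in the data. The recovery and false calls of probes hold for few changes, balanced in direction, between groups of like intensity distribution. The data had far more changes and unlike distributions, so these figures need not hold for them.

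Alternatives set before the data were examined were the replicate number as a fixed or random block, median centring, no scaling, cyclic loess, an offset of 50, leaving out the dimmest 25% of probes, probes with all 12 values, an intensity trend or robust variance, array weights, averaging the probes of 1 gene, leaving out each sample and each pair, and for lists fry and an estimated correlation. Alternatives added after seeing the data were the averaged sets with and without a block, leaving out samples 1 and 2 of both groups, an offset of 0.05 that keeps zeros, values of 100 as missing, removal of a running median over probe numbers, and a robust straight line that brings each array onto the mean water array.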

Results

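RNA abundance was measured on arrays in wild-type Arabidopsis thaliana plants of the ecotype Wassilevskija. In 6 samples plants had been treated with water, and in 6 samples they had been treated for 30 min in MS, a plant salt medium, containing 60 mM sucrose. The table held 1 intensity per probe and sample for 3439 probes, on a scale from 0 to 100. The single comparison of the design asks which transcripts differ between plants in sucrose medium and plants in water. Medium salts and sucrose were given together, so the comparison covers both. The labels do not say whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

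Among probes that name 1 gene and have a value in all 12 samples, the largest increases in sucrose medium included a guanylate kinase family gene, a carbohydrate kinase gene, a PsbP-domain gene and a gene of histidine synthesis. AT3G06200, a guanylate kinase family gene, was 14.5-fold higher, from a log2 intensity of 0.09 ± 0.09 in water to 3.94 ± 0.21 in sucrose medium (SD, n = 6 each; limma, adjusted p = 7.6e-11). AT1G06730, which encodes a carbohydrate kinase of the pfkB family, was 11.3-fold higher (log2 intensity -0.63 ± 0.48 in water and 2.87 ± 0.98 in sucrose medium; adjusted p = 1.07e-05), and sucrose replicate 3 lay far below its other samples at 0.88. AT1G76450, which encodes a PsbP-domain protein, was 10.6-fold higher (adjusted p = 6.36e-09). AT-HF (AT4G26900, also called HISN4), which encodes imidazole glycerol phosphate synthase of histidine synthesis, was 6.92-fold higher, from a log2 intensity of -1.78 ± 0.09 to 1.01 ± 0.20. The sizes depend on the scaling: with median centring the log2 fold changes of AT3G06200, AT1G06730, AT1G76450 and AT-HF were 2.64, 2.62, 2.46 and 2.21, against 3.85, 3.498, 3.41 and 2.79 with quantile normalisation.

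The other genes among the 12 largest increases of these probes were AT4G18180, AT1G12800, AGL54 (AT5G27090), AT2G36480, AT5G40030, AT5G06010, AT2G46910 and AT3G44570, with log2 fold changes of 3.56, 2.85, 2.69, 2.58, 2.28, 2.18, 2.01 and 1.97. AT1G12800 encodes a protein with an S1 RNA-binding domain, and AGL54 a MADS-domain transcription factor. AGL54 was dim in water and varied there, at -3.65 ± 1.98 against -0.95 ± 0.23 in sucrose medium (SD, n = 6 each; limma, adjusted p = 0.00642). Its water replicate 2 lay at -7.63 against a group median of -2.89, which lowers its mean in water. Each of these 12 genes was higher in 6 of 6 same-numbered sample pairs. With median centring all 12 were past the threshold as higher, from 1.16 for AT5G06010 to 2.99 for AT4G18180, and AT1G12800 and AT5G40030 were at 1.85 and 1.38.

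The largest decreases among the same kind of probes, relative to the other probes of the array, included AT3G56010 and single genes for a subunit of ferredoxin-thioredoxin reductase, a plastid sugar phosphate translocator and a thylakoid protein. AT3G56010 fell most, from a log2 intensity of -1.93 ± 0.27 in water to -4.73 ± 0.85 in sucrose medium (SD, n = 6 each; limma, adjusted p = 1.2e-05), a 6.98-fold difference. AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, was 3.79-fold lower (log2 fold change -1.92 ± 0.12, SE; adjusted p = 6.39e-08). AT5G17630, the plastid xylulose 5-phosphate translocator, was 3.24-fold lower (adjusted p = 4.39e-06). FZL (AT1G03160), a dynamin-related protein of thylakoid membranes, was 3.21-fold lower (adjusted p = 2.34e-05). Without scaling AT5G17630 and FZL were at -0.24 and -0.19, and neither was past the threshold (limma, adjusted p = 0.0708 and 0.191). Both were dim, with mean deposited intensities of 0.108 and 0.117 in water and 0.091 and 0.102 in sucrose medium.

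AT4G24160, a homologue of the lipid droplet regulator CGI-58, had a log2 fold change of -1.92 ± 0.67 (SE; limma, adjusted p = 0.0236); without sucrose replicate 2 it was -1.63 (adjusted p = 0.0535), and with 3 averaged sets of samples per group its adjusted p was 0.114. AT2G42490, which encodes a copper amine oxidase, AT1G51080, AT3G07790, APTX (AT5G01310), TPP2 (AT4G20850, tripeptidyl peptidase II), AT4G20690 and AT1G01500 had log2 fold changes of -1.68, -1.56, -1.55, -1.50, -1.49, -1.42 and -1.40. On the linear deposited scale the mean of AT4G24160 was not lower, at 0.112 in water and 0.121 in sucrose medium. After quantile normalisation all 12 genes were lower in 6 of 6 pairs. Without scaling they stayed below 0, between -1.21 for AT3G56010 and -0.04 for AT2G42490, while the median over all probes tested was 1.09, and 7 of them were then no longer past the threshold.

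**Figure D1:**
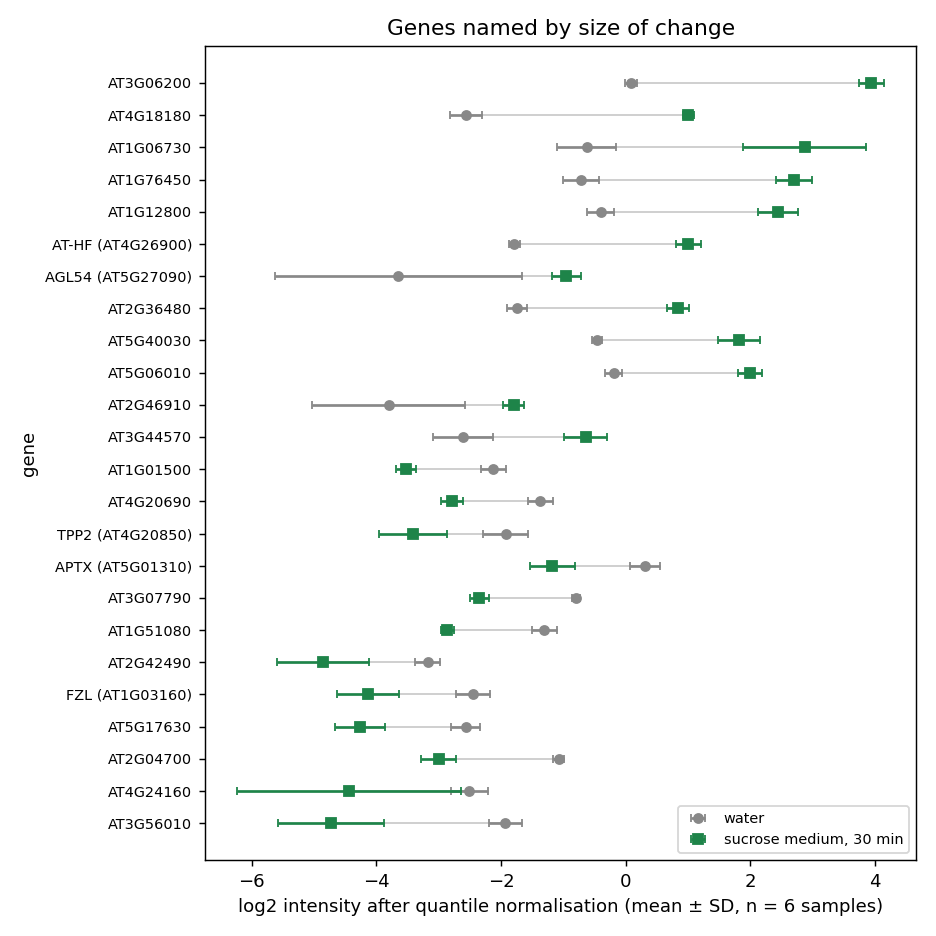
Log2 intensity after quantile normalisation (x axis) of the 24 genes named by size of change (y axis); circles are water and squares sucrose medium, each the mean of 6 samples with SD bars. AT3G06200 rose from 0.09 to 3.94, and the widest bars belong to AGL54 in water (SD 1.98) and AT4G24160 in sucrose medium (SD 1.79).

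Across all probes, 1878 of 2915 tested differed between the groups (64.4%; limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 918 were higher and 960 lower in sucrose medium after quantile normalisation, so 48.9% were higher. Without scaling 90.5% of 2380 probes past the threshold were higher, with median centring 40.0% of 2016, and with each array brought onto the mean water array by a straight line 74.0% of 1385, out of 2105 probes that could then be tested. At least a 2-fold increase was seen for 285 of the probes past the threshold, and at least a 2-fold decrease for 279. Of 587 tested probes that name 1 gene, 207 were higher and 177 lower.

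Of the 28 gene lists fixed before the data were examined, 3 had any member on a tested probe that names 1 gene. In the photosynthesis list 3 of 42 genes were measured, and 1 passed the threshold, both over all probes and adjusted over the list alone. PSBY (AT1G67740), a photosystem II subunit, fell by 0.79 on the log2 scale (SE 0.11; limma, adjusted p = 3.97e-05), in 6 of 6 pairs; with median centring it was at -1.59 and without scaling at -0.33. PSAN (AT5G64040) of photosystem I had -0.24 ± 0.12 (adjusted p = 0.0901) and PSBW (AT2G30570) of photosystem II 0.05 ± 0.12 (adjusted p = 0.745). PSAN passed without sucrose replicate 1 (adjusted p = 0.0449) and without water replicate 6 (adjusted p = 0.0296), and with the replicate number as a block (adjusted p = 0.0229), but not with averaged sets (adjusted p = 0.275). With median centring both were past the threshold as lower, PSAN at -1.48 (adjusted p = 4.42e-07) and PSBW at -1.74 (adjusted p = 1.26e-08), and PSBW also without scaling, at -0.48 (adjusted p = 0.000443), and with values of 100 as missing, at -0.43 (adjusted p = 0.0204). The list did not stand apart from the other genes (camera, p = 0.243, and p = 0.265 with an estimated correlation), although it did with median centring, where its median was -1.59, and without scaling, where its median was -0.33. In both settings bright probes were lower relative to dim ones. Without scaling the median difference was -0.42 in the brightest 5% of probes and 1.35 in the dimmest 25%. PSBY, PSAN and PSBW had mean log2 intensities of 0.64, 1.44 and 5.21 in water, so the list cannot be told apart from bright probes there. The Calvin cycle list had 1 measured gene, PRK (AT1G32060, phosphoribulokinase), which was 2.07-fold lower (log2 fold change -1.05 ± 0.14, SE; adjusted p = 2.65e-05) and passed adjusted over the list alone; with median centring it was at -1.94 and without scaling at -0.68. The hypoxia list had LDH (AT4G17260, lactate dehydrogenase) at -0.90 ± 0.60 (adjusted p = 0.204), with 0 genes past the threshold adjusted over the list alone; without scaling its log2 fold change was above 0, with median centring it was -0.26, and with 0.05 added before log2, which keeps zeros, it passed at -0.42 (adjusted p = 0.00595).

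Because few genes of those lists were measured, 14 further groups were written from the names of genes on the array, after values of the most changed genes had been seen. They hold 99 measured genes, of which 31 were higher, 33 lower and 35 not past the threshold. With the replicate number as a block 37 were higher and 35 lower, and with averaged sets 20 higher and 21 lower. In the main fit 64.4% of all probes tested passed the threshold, and 65.4% of those that name 1 gene. Of all 2915 probes tested, 2024 passed with the block and 1366 with averaged sets. The count over the 99 genes therefore does not set them apart. Counts within a group are to be read against the values over all probes from the same fit. Sizes depend on the scaling here too: with median centring AT5G14590, AT1G24360, AT1G74470 and AT4G09620 were at -1.08, -1.14, -1.39 and -1.30, and AT5G15280 at 5.46. By camera 0 of the 14 groups stood apart from the other genes at adjusted p under 0.05, and 2 did at unadjusted p under 0.05. By fry, which asks whether the genes of a group move on balance one way, 7 passed. That test does not compare a group with the other genes, most of which also changed.

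In the plastid redox group 5 of 6 genes were higher in sucrose medium and 1 was lower (camera adjusted p = 0.792); with averaged sets 3 were higher and 1 lower. The higher genes included SRX (AT1G31170), sulfiredoxin, with a log2 fold change of 1.24 ± 0.25, AT3G52960, a peroxiredoxin, with 0.87 ± 0.14, and NTRC (AT2G41680), the plastid NADPH-dependent thioredoxin reductase, with 0.62 ± 0.11 (SE; limma, adjusted p = 0.000909, 0.00012 and 0.000322). The lower gene was AT2G04700, described above. All of these directions held with median centring.

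In the fatty acid and lipid group 3 of 5 genes were lower and 0 higher (camera p = 0.0445, adjusted p = 0.312, and adjusted p = 0.470 with an estimated correlation). FATB (AT1G08510), the acyl-ACP thioesterase that releases saturated fatty acids, fell by 1.37 on the log2 scale (SE 0.17; limma, adjusted p = 2.27e-05), but was not past the threshold without scaling (-0.09, adjusted p = 0.701). AT5G16230, an acyl-ACP desaturase, and AT1G24360, a ketoacyl-ACP reductase, had -0.68 ± 0.10 and -0.46 ± 0.08, and both were above 0 without scaling, at 0.63 and 0.12 against the median of 1.09 over all probes. With the straight-line scaling AT1G24360 was at 0.10.

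In the group of amino acid, nucleotide and cofactor synthesis 5 of 9 genes were lower and 1 higher, AT-HF (camera adjusted p = 0.792); with averaged sets 3 were lower and 1 higher, and with the block 5 lower and 2 higher. The group's median was -0.55 and its fry direction was up, so they differ in sign. THIC (AT2G29630), which makes the pyrimidine part of thiamin, had a log2 fold change of -0.84 ± 0.14, AT2G44530, a phosphoribosyl diphosphate synthase, -0.64 ± 0.11, and AT3G58610, ketol-acid reductoisomerase of branched-chain amino acid synthesis, -0.55 ± 0.11 (SE; limma, adjusted p = 0.000225, 0.000337 and 0.000971). Without scaling these 3 genes were above 0, at 0.18, 0.65 and 0.67, and so below the median of all probes, and THIC was not past the threshold with the straight line (-0.48, adjusted p = 0.0911).

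The central carbon metabolism group had 2 higher and 4 lower genes of 10 (camera adjusted p = 0.792), 2 and 2 with averaged sets, and 3 and 4 with the block. It includes AT1G06730, PRK and AT5G17630, described above, and AT5G14590, an isocitrate dehydrogenase, at -0.45 ± 0.11 (SE; limma, adjusted p = 0.00297), which was above 0 without scaling (0.18) and with the straight-line scaling (0.14) and not past the threshold with cyclic loess (adjusted p = 0.0748) or averaged sets (adjusted p = 0.0576). The light reactions group had 2 higher and 3 lower genes of 13 (camera adjusted p = 0.792), and 2 and 3 with averaged sets. With the block it had 2 and 5, where PSAN and 1 other gene also passed as lower. Without scaling, where bright probes were lower relative to dim ones, the group stood apart as lower (camera adjusted p = 0.0301). Besides AT1G76450 and PSBY, AT1G54500, a rubredoxin-like protein, had a log2 fold change of -1.29 ± 0.08, LPA19 (AT1G05385), a photosystem II assembly factor, -0.92 ± 0.10, and AT1G22700, a photosystem I assembly factor, 0.77 ± 0.10 (SE; limma, adjusted p = 4.67e-08, 8.88e-06 and 3.19e-05). LPA19 was at 0.38 without scaling. The tetrapyrrole and carotenoid group had 1 higher and 2 lower genes of 5 (camera adjusted p = 0.955), and 1 and 1 with averaged sets. Z-ISO (AT1G10830), an isomerase of carotenoid synthesis, rose (1.42 ± 0.26), and SIRB (AT1G50170), of sirohaem synthesis, and AT1G74470, geranylgeranyl reductase, had -0.59 ± 0.11 and -0.31 ± 0.09. SIRB was at 0.72 without scaling, and AT1G74470 at 0.03 with the straight-line scaling; AT1G74470 was also not past the threshold without scaling (adjusted p = 0.176), with cyclic loess (adjusted p = 0.140) or with averaged sets (adjusted p = 0.0845).

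Genes of organelle gene expression went both ways. Of 15 pentatricopeptide repeat genes, whose proteins bind organelle RNA, 7 were higher and 5 lower (camera adjusted p = 0.955), with averaged sets 3 and 2, and with the block 8 and 4. AT5G15280 had the largest increase of the group, with a log2 fold change of 4.83 ± 0.31 (SE; limma, adjusted p = 4.21e-07), measured against the 4 of 6 water samples in which it was above 0. AT2G46050 and AT1G79080 rose by 1.84 and 0.72, and CRR21 (AT5G55740), an RNA editing factor, had -0.999 ± 0.205, which without scaling was 0.17. Of 6 mTERF genes, named for mitochondrial transcription termination factors, 3 were higher and 2 lower (camera adjusted p = 0.955), with averaged sets 0 and 1, and with the block 4 and 2, among them AT3G46950 at 0.68 ± 0.19 and AT4G09620 at -0.64 ± 0.09. AT3G46950 was not past the threshold with median centring (0.32, adjusted p = 0.127) or averaged sets (adjusted p = 0.0654), nor AT4G09620 without scaling (-0.04, adjusted p = 0.703) or with the straight line (-0.09, adjusted p = 0.474). AT5G55580 had -0.32 ± 0.09, and was at 0.40 without scaling and at 0.34 with the straight-line scaling, and not past the threshold with cyclic loess (adjusted p = 0.146) or averaged sets (adjusted p = 0.0908). Of 4 plastid ribosomal genes 2 were higher and 1 lower (camera adjusted p = 0.955), with averaged sets 1 and 2, and with the block 2 and 2. AT5G65220, of the large subunit, had 1.46 ± 0.15, but 0.10 with median centring, where it was not past the threshold, and AT4G01310 had -0.38 ± 0.10, and 0.81 without scaling. In the plastid protein folding and proteolysis group 0 of 5 genes passed the threshold (camera adjusted p = 0.955), with log2 fold changes from -0.50 for AT5G46390 to 0.20 for SECE1 (AT4G14870), which passed without sucrose replicate 1 (0.28, adjusted p = 0.0358) and with the replicate number as a fixed block (adjusted p = 0.048), but not as a random block (adjusted p = 0.0738) or with averaged sets (adjusted p = 0.326). SECE1 also passed without scaling, at 1.35 where the median of all probes was 1.09, and with the straight line, at 0.94. AT5G46390 was at 1.08 with the straight line (adjusted p = 0.00998). AT1G24240 of the ribosomal group, at -1.32 ± 0.79 (adjusted p = 0.161), passed with the block (adjusted p = 0.00269) and with averaged sets (adjusted p = 0.0148).

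**Figure D2:**
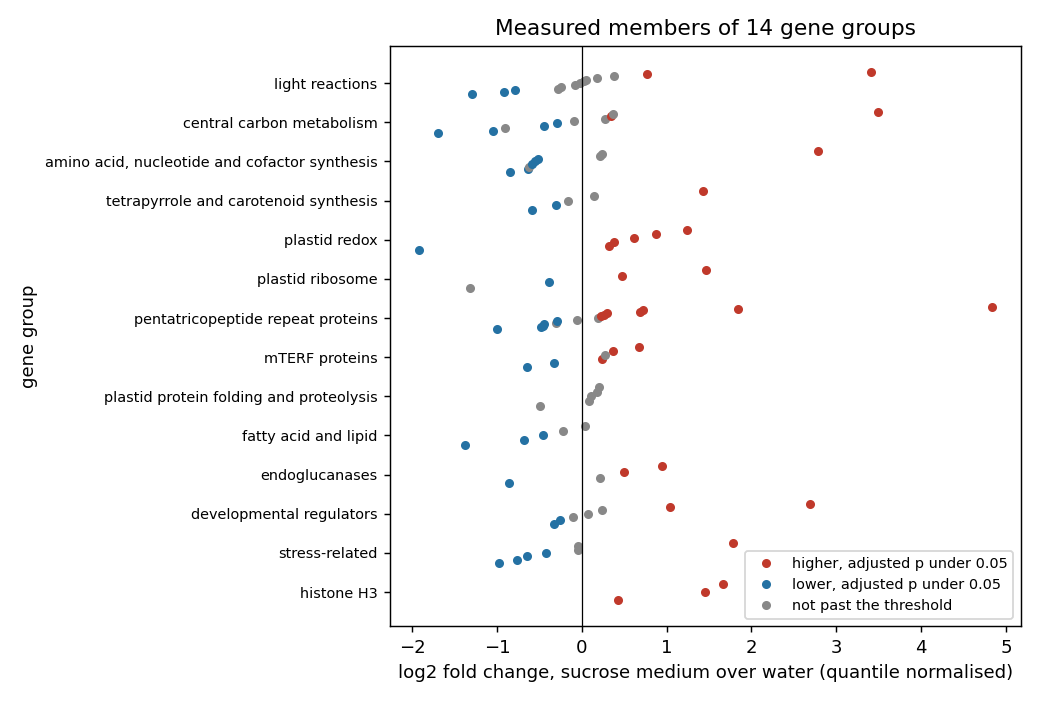
Log2 fold change of sucrose medium over water (x axis, quantile normalised) for the measured members of 14 gene groups (y axis); each point is 1 gene, red and blue points passed adjusted p under 0.05 and grey points did not. All 3 histone H3 genes lie above 0, 5 of 6 plastid redox genes are red, and 0 of 5 plastid protein folding genes passed.

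The 2 groups of arrays also differed in their deposited intensities. The median intensity of a sample was 0.177 ± 0.008 in water and 0.440 ± 0.015 in sucrose medium (SD, n = 6 each; exact permutation test, two-sided p = 0.0022, the smallest that 924 splits allow). This treats the 12 samples as independent. With the sign of each pair's difference permuted the p-value was 0.031, and with 3 averaged sets per group 0.1, the smallest possible in either case, for this measure and both measures below. Values of 0 numbered 484 ± 21 per water sample and 439 ± 14 per sucrose sample (exact permutation p = 0.0043), and values at the top of the scale 6.17 ± 1.17 and 1.83 ± 0.41 (exact permutation p = 0.0022). The unscaled difference depended on brightness. Its median was 1.35 on the log2 scale in the dimmest 25% of probes and -0.42 in the brightest 5%, of which 80.8% were lower in sucrose medium.

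**Figure D3:**
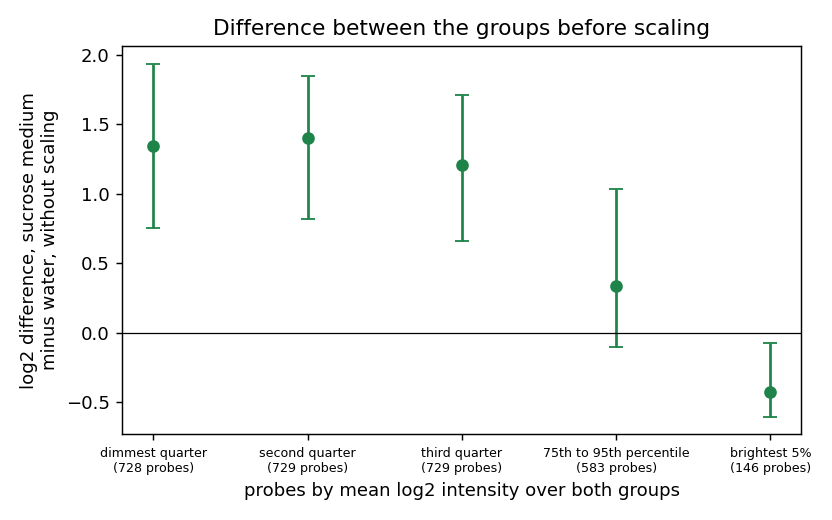
Unscaled log2 difference of sucrose medium minus water (y axis) for 2915 probes in bins of mean log2 intensity (x axis); points are medians and bars span the 25th to 75th percentile of probes. The median falls from 1.35 in the dimmest bin to -0.42 in the brightest 5%.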

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

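In 164 groups of 6 values, of array measures and of named genes, 14 had 1 sample far from the other 5, where chance alone gives about 1 in 20. Sucrose replicate 1 had 468 values of 0 against a median of 434.5 in its group, and sucrose replicate 2 had 1 value at 100 where the other sucrose samples had 2.

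Among the named genes, sucrose replicate 3 stood apart for AT1G06730 at a log2 intensity of 0.88 against a group median of 3.21, and water replicate 3 stood apart for it at -1.56 against -0.53. AGL54 (AT5G27090) was at -7.63 in water replicate 2 against -2.89, AT5G06010 at 2.39 in sucrose replicate 6 against 1.94, and TPP2 (AT4G20850) at -4.45 in sucrose replicate 5 against -3.25. Water replicate 1 stood apart for AT2G44530 at -1.85, for AT5G46390 at -2.62 and for AT5G26880 at -0.69, with group medians of -1.46, -1.23 and -0.45. CRR21 (AT5G55740) was at -1.79 in water replicate 4 against -0.77, and MAMI (AT5G54110) at -0.0021 in water replicate 5 against 0.10. Sucrose replicate 4 stood apart for AT5G55580 at -0.010 against -0.43 and for SIS (AT5G02020) at -2.87 against -2.06.

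Probes at 0 throughout a group were outside the comparison. Of these, 21 were 0 in all 6 water samples and above 0 in all 6 sucrose samples, and 0 were the other way. Their mean intensity in sucrose medium ran from 0.041 to 1.33, with a median of 0.224. The 2 that name 1 gene, AT1G72890 at 0.242 ± 0.111 and AT4G05030 at 0.076 ± 0.040 (SD, n = 6), were chosen after their values were seen and are listed at 0 in water.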

How the results depend on the processing

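The straight line, averaged sets, samples 1 and 2 left out, offset of 0.05, values at 100 and running median were chosen after the data were seen. The count of 1878 probes stayed within 1.5 times under all alternatives run, from 1366 with averaged sets to 2380 without scaling; it was 1796 to 1857 without 1 sample, and with the paired fit (replicate block) 2024, or 1898 to 1937 without 1 pair. Of the 1878, 1535 were called without scaling, 442 of them in the opposite direction, 1716 with median centring, 39 opposite, and 1036 with the straight line, 54 opposite. The block changed no call of a gene named by size and no list call; of the 77 genes followed 3 gained a call with it, and of all 99 members of the added groups 9 gained and 1 lost a call; with averaged sets 1 gained and 24 lost. The share of higher probes was 48.9% (95% Wilson interval 46.6 to 51.1, which treats probes as independent). Quantile normalisation gives all arrays the same distribution and so tends to balance higher and lower probes. The share moved to 40.0% with median centring, 90.5% without scaling, 74.0% with a straight line, and 46.5% with either offset. The cause of these moves was not tested. Of the fixed lists 0 passed, and photosynthesis (1 list) passed as lower with median centring and without scaling, and 1 list passed by fry. Bright probes were lower relative to dim ones in those 2 scalings, and the measured photosynthesis genes were bright. Of the 14 added groups 0 passed, 1 (light reactions) without scaling and 7 by fry, which asks another question than camera.

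Of 77 genes followed, 35 were called lower. Without scaling 17 of these turned to above 0, each by less than the median of 1.09 over all probes, and of the 12 genes named as lower by size 5 kept their call; calls of higher genes could hardly be lost there, as most probes rose. The 17 were AT1G05385 (0.38), AT1G24360 (0.12), AT1G50170 (0.72), AT2G29630 (0.18), AT2G44530 (0.65), AT2G44570 (0.40), AT3G17600 (0.76), AT3G58610 (0.67), AT4G01310 (0.81), AT4G15910 (0.35), AT5G02020 (0.48), AT5G14590 (0.18), AT5G16230 (0.63), AT5G26880 (0.60), AT5G54110 (0.077), AT5G55580 (0.40) and AT5G55740 (0.17). Of genes not past the threshold, AT4G17260 (1.0005), AT4G25080 (1.12), AT2G04540 (1.11) and AT5G46390 (0.64) turned to above 0 without scaling, and AT2G30570 to below 0 (-0.48; -1.74 with median centring, -0.43 with values at 100 as missing). The straight line gave a value for 54 of the 77 genes, 13 of the 24 named by size among them. All 29 genes called higher that had a value kept their call. Of the 35 called lower, 9 kept it, 3 lost it, 7 turned to above 0 and the rest had no value. Many decreases could therefore not be checked with the straight line. The 7 that turned were AT1G24360 (0.10), AT1G74470 (0.034), AT3G17600 (0.43), AT4G01310 (0.038), AT5G14590 (0.14), AT5G26880 (0.37) and AT5G55580 (0.34). Of genes not past the threshold, AT5G46390 (1.08), AT5G64040 (0.049) and AT2G30570 (-0.014) turned. The cause was not tested. Near 0, AT2G30570 also changed sign without sucrose replicate 3 or 6 (-0.0099 to 0.11 over single samples) and without pair 3 or 6 (-0.011 and -0.0086), AT2G32990 with an offset of 50 (-0.00013), an offset of 0.05 (-0.034) and without pair 3 (-0.12), and AT5G46390 without samples 1 and 2 (0.016). AT4G17260 gained a call with the offset of 0.05 (-0.42). With averaged sets 11 of the 77 genes lost their call and 1 gained it. How far dim probes lie above background is unknown, which limits fold changes among them.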

Other observations

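Of the tests on the origin of the patterns, those on neighbouring probes, on the straight line and on other splits of the samples were fixed before their result was seen, and the others after. The groups in the first paragraph were written after values of the most changed genes had been seen.

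All 3 measured histone H3 genes were higher in sucrose medium, AT1G13370 by 1.67 ± 0.10, AT5G65360 by 1.46 ± 0.11 and AT1G09200 by 0.43 ± 0.10 on the log2 scale (SE, 6 of 6 pairs each), and with median centring they were at 0.80, 1.39 and 0.42. AT1G09200 was not past the threshold with averaged sets (adjusted p = 0.0573). The group did not pass after adjustment (camera p = 0.0145, adjusted p = 0.204, and adjusted p = 0.470 with an estimated correlation). Histone H3 genes are nearly identical in sequence, so their probes can share signal and may not be 3 separate measurements, which was not tested. In the stress-related group 1 of 7 genes was higher and 4 lower (camera adjusted p = 0.792), and 1 and 2 with averaged sets. DRT101 (AT5G18070) was at 1.78 ± 0.19, and the drought-induced DI21 (AT4G15910), the mannitol-induced MAMI (AT5G54110) and the salt-induced SIS (AT5G02020) were at -0.98 ± 0.17, -0.64 ± 0.11 and -0.77 ± 0.22; without scaling these 3 were above 0, at 0.35, 0.08 and 0.48. SIS was not past the threshold with averaged sets (adjusted p = 0.0544), nor MAMI with the straight line (-0.054, adjusted p = 0.751).

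Among 7 developmental regulators 2 were higher and 2 lower (camera adjusted p = 0.955), 2 and 0 with averaged sets, and 3 and 2 with the block. LAS (AT1G55580), a GRAS regulator of axillary meristems, was at 1.04 ± 0.13 and AGL54 at 2.69 ± 0.73. AGL26 (AT5G26880) was at -0.33 ± 0.08 and IAA31 (AT3G17600) at -0.26 ± 0.10 (limma, adjusted p = 0.0429). Both were above 0 without scaling, at 0.60 and 0.76, and with the straight line, at 0.37 and 0.43. AGL26 was placed in this group by its name, and what it encodes was not checked. The call of IAA31 was lost without any 1 of water replicates 1, 2, 3, 4 and 6 and of sucrose replicates 1, 2 and 5, with log2 fold changes of -0.27, -0.25, -0.23, -0.23, -0.26, -0.22, -0.22 and -0.27, and with averaged sets (adjusted p = 0.203), as was that of AGL26 (adjusted p = 0.0507). Of 4 endoglucanase genes, of cell wall hydrolysis, 2 were higher and 1 lower (camera adjusted p = 0.955). GH9B16 (AT4G38990) and GH9B11 (AT2G44560) were at 0.95 ± 0.08 and 0.50 ± 0.11, and GH9B12 (AT2G44570) at -0.86 ± 0.08, which without scaling was 0.40.

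A large share of probes differed between the groups, 1878 of 2915, or 1366 with 3 averaged values per group. If the 12 samples were independent, which their likeness within sets of 2 goes against, other splits of them would argue against chance as the source. Of 100 drawn splits of the 12 samples 1, the real one, gave as many, and the highest other count was 1. Of the 32 splits that part all 6 pairs, fitted with the block, 1 gave as many as the real 2024, and the highest other count was 2. If the sets of 2 are repeat measurements, the 10 splits of the 6 averaged sets are too few for a share under 0.05; 1 gave as many as the real 1366, and the highest other count was 0. A smooth brightness-dependent difference between arrays is argued against as the whole cause by 1794 probes after cyclic loess, which removes such a curve. Quantile normalisation also acts on such a difference, so the likeness of 1794 to 1878 adds nothing. Repeat measurements are argued against as the whole cause by 1366 probes with 3 averaged values per group. After the straight-line correction for a scale factor with a constant background, 1385 of the 2105 probes that could be tested passed. This count does not decide on that explanation, because the fitted background is not a floor. Taking off a misplaced background can itself make dim probes differ. Of these 2105, 1425 were among the 1878; 1036 of them were among the 1385, 982 in the same direction. Position on the array, as far as probe numbers follow it, is argued against by a correlation of 0.020 between fold changes of neighbouring probe numbers, within the range of -0.079 to 0.087 of 1000 shuffles. Of all 2915 probes tested, 62.2% had the same sign in all 6 pairs, where random signs in independent pairs would give 3.1%. Over the 3 sets of 2 samples 76.0% had the same sign, where random signs would give 25%. A steady difference between the 2 groups of arrays would keep signs too, so these shares do not tell the origin. A response to medium and sucrose, given together, stays open; the labels name no batch that could be tested.

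Without scaling most probes were higher in sucrose medium, with a median log2 difference of 1.09. One scale factor per array is argued against by the difference of -1.16 between the brightest 25% and the dimmest 25% of probes, which was -1.25 to -0.92 over the 36 array pairs. A constant background added to the sucrose arrays is argued against by the brightest 5% of probes, 80.8% of which were lower in sucrose medium. For a factor and a constant background together, under 5% of values above 0 on a sucrose array were predicted to lie below the fitted background. On each sucrose array at least 26.3% did. The fitted background is the intercept of a robust line, which spots scatter round, and not a floor. The result therefore does not decide the question, and this explanation stays open. A background that varies between spots and a real rise of dim transcripts in sucrose medium were not tested and stay open.

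Sucrose replicates 1 and 2 were less like sucrose replicates 3 to 6 than these were like each other. Spearman correlations across probes of replicates 1 and 2 were 0.915 to 0.921 with replicates 3 and 4 and 0.916 to 0.921 with replicates 5 and 6, against 0.957 to 0.959 between replicates 3 and 4 and replicates 5 and 6. In water the same ranges were 0.926 to 0.935, 0.916 to 0.926 and 0.940 to 0.948. Leaving out samples 1 and 2 of both groups gave 1785 probes. Fold changes computed within samples 1 and 2, 3 and 4, and 5 and 6 correlated across probes at 0.77, 0.73 and 0.84. Of the probes past the threshold without 1 set, 94.2% to 97.5% had the same sign in the set left out, where random signs would give 50%.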
